A study of Mus musculus with 8 samples.

How the data were processed

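Per the labels' protocols, cells were grown to confluence for 48 hours, RNA was isolated from cell pellets with removal of genomic DNA, and polyA-selected libraries were sequenced on an Illumina NovaSeq sequencer. The RNA quality number was 10.0 for every sample, per the labels' protocols. The submitters' processing notes name fastp 0.23.2, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 2.11.40.6, with the mouse builds mm10 and GRCm38. Those notes give no role or order for the tools.

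The supplied file was 1 table with a column of Entrez gene identifiers and 8 value columns whose headers say featureCounts, per the file headers. Its file name calls the values normalised counts, and the unit plays no part here, since no value was used. Before any test was run, the identifiers and the column names were compared with the labels, using Python 3.11.15. Identifiers were looked up by exact match in the RefSeq gene table of GRCm38.p6 and in the Entrez table of GENCODE release M21, both of mouse. Column names were compared with the sample titles. Gene symbols of the fixed lists were turned into mouse identifiers through the symbols and synonyms of the RefSeq gene table.

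The table failed both comparisons, so all 8 value columns were left out. The 4 columns named sgCtrl end in the titles of the 4 control libraries, but their rows carry no mouse gene identifier, and they were not taken as those libraries. The 4 columns named sgANXA4 match no title, and giving them to the knockout libraries by their order would have been a guess. The agreement of the knockout lines, each against a separate control line, was fixed before the data were examined and was not run. The tests of 37 gene lists, also fixed then, were not run either. Nor were the 3 other comparisons of expression fixed then (knockout against control lines, Control 1 against Control 2, and Actr3 KO-1 against Actr3 KO-2). The rule for choosing named genes depended on those comparisons except for Actr3 and the Arp2/3 subunits. Actb, Gapdh and Aqp2 were named after the table was seen, as further examples of identifiers looked up.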

Results

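The study was designed around Actr3, the gene of the Arp3 subunit of the Arp2/3 complex, which nucleates branched actin filaments. Its cells were mIMCD3, an established mouse epithelial line from the inner medullary collecting duct of the kidney. The labels describe 8 polyA RNA libraries from 4 derived lines. Control 1 and Control 2 carried the wild type control genotype and Actr3 KO-1 and Actr3 KO-2 the Actr3 knockout genotype, with 2 libraries from each line and so 4 libraries per genotype. The question the design poses is which transcripts differ between Actr3 knockout and control lines, and whether both knockout lines differ from the controls alike.

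The table supplied with the series did not match these samples, and no expression value from it is reported. Of its 8 value columns, 4 were named sgCtrl and 4 were named sgANXA4, after a different gene from the one in the labels. The sgCtrl names end in the titles of the 4 control libraries, but the number of columns whose whole name is a sample title was 0. The number of columns named for Actr3 was 0. The labels give mouse as the organism, and the gene identifiers were not found among those of mouse. The table listed 28395 identifiers in a column headed as Entrez identifiers, and 0 of them occurred among the 49997 gene identifiers of the mouse RefSeq annotation of GRCm38.p6. The Entrez identifiers of GENCODE release M21, also a mouse annotation, gave 0 matches among 22414. For comparison, 22324 of those 22414 GENCODE identifiers (99.6%) were found in the RefSeq annotation. The identifiers were not looked up in any other organism.

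No mouse identifier of Actr3 or of any other gene looked up by name was among the identifiers listed. Actr3 has the mouse identifier 74117, and it was not among those listed. In the Arp2/3 complex list as a whole, Actr3 included, 10 of 10 members had a mouse identifier and 0 were listed. They include Actr2 (66713), the second actin-related subunit, and Arpc2 (76709), a core subunit. Actb (11461) and Gapdh (14433), which are abundant in most cells, and Aqp2 (11827), the vasopressin-regulated water channel of the collecting duct, were not listed either. Across the 37 gene lists fixed before the data were examined, 844 of 857 genes had a mouse identifier and 0 of the 844 were listed. The mouse identifiers of all these genes came from the same RefSeq annotation that gave 0 matches. Their absence therefore follows from that count and is no separate evidence.

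No comparison of Actr3 knockout with control lines, of one control line with the other, or of one knockout line with the other was therefore made. The level of Actr3 in the knockout libraries, the depth of each library and the spread between the libraries of a line are not reported here.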

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

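The count of mouse identifiers in the table was 0 with the RefSeq annotation and 0 with the GENCODE Entrez table, the second lookup. Neither lookup was among the tests fixed before the data were examined, and the second was chosen after the table had been seen. Since 99.6% of the GENCODE identifiers are also in the RefSeq annotation, the second count was nearly fixed by the first. The tests fixed before the data were examined were not run, since no value column was tied to a library of the study. For the same reason no other pseudocount, filter or normalisation was tried, and no fit without a library or a line was made. No paired analysis was possible because no column of the table was matched to a library with a replicate number.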

Other observations

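The test described here was chosen after the mismatch had been seen. The column names and the labels name different targets, ANXA4 and Actr3. If the columns carry wrong names but hold mouse genes, most of the identifiers would be mouse identifiers. Of the 28395 gene identifiers, 0 were mouse identifiers in the RefSeq annotation, so the identifiers as given were not those of mouse genes. That count was itself part of the mismatch, so its outcome was known when the test was chosen. It covers the identifiers only, since no value was read. The same count was the reason for leaving out the columns named sgCtrl, but no conclusion about misnamed columns is drawn from it. A candidate explanation is that a table from another experiment was deposited with this series. That remains a hypothesis, because it rests on column names and gene identifiers alone. No expression value enters either of them, so the mismatch says nothing about the biology of the cells.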
